A study of Mus musculus with 2 samples.

How the data were processed

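Total RNA depleted of ribosomal RNA was sequenced from the nuclear fraction, described as nucleoplasmic in the labels, of bone-marrow-derived macrophages of C57BL/6J mice. Both libraries belong to 1 group: cells that met Lipid A at 100 ng/ml for 12 h, rested for 12 h without it and met it again at 100 ng/ml for 40 min before collection. The labels call the 2 libraries biological replicates 1 and 2. They give the same donor entry for both, so the spread between them may be smaller than the spread between animals. Library 1 was made from 1 µg of RNA and library 2 from 500 ng, per the labels, and this difference cannot be separated from the replicate number. The sex of the animals was not collected, per the labels.

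Each library came with 3 tables, a gene table and a transcript table in the column layout of RSEM and a transcript table in the column layout of kallisto. The submitters' notes beside the files name the mm10 assembly and the GENCODE M21 annotation. The program versions and the aligner are not given in the sources used here. The expected count of each gene and transcript was used as the authors deposited it, a maximum-likelihood estimate that need not be whole. TPM and FPKM are the authors' own length-scaled values, per the file headers, and TPM was computed over all features of the table, short RNAs included. The bounds of the TPM credibility interval, a score of the precision of each estimate, were deposited by the authors without a stated level. The percent of each gene's TPM in a transcript was deposited by the authors and was recomputed here from transcript TPM.

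All 55536 genes with Ensembl identifiers matched the M21 annotation used for symbols, RNA classes and coordinates. The tables also held 26248 short features with numeric identifiers and no gene name, 96 ERCC spike-in sequences and the phiX genome. These were kept out of library sizes and tests. PhiX took 0.653% of the expected counts of library 1 and 0.221% of those of library 2, the numeric features took 20 and 43 counts, and the ERCC sequences took 0. A total of 86 genes had no transcript in the kallisto table. Where 2 genes carried the same symbol, the one with more counts was used.

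Library 1 held 19797829 expected counts on named genes and library 2 held 17213606. A gene with 0 counts may hold up to 3 counts, which is 0.152 CPM in library 1 and 0.174 CPM in library 2. Shares of counts carry Wilson 95% intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Genes that overlap, or that have near-identical copies such as pseudogenes, share reads, and their values are uncertain. The sources used here do not state whether counting used the strand.

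A gene was called detected at 10 or more expected counts in both libraries. Values other than list levels are given as the mean and SD over the 2 libraries. For TPM these are the deposited values without centring, so the SD also includes the shift of the TPM scale between the libraries. With 1 group no test between conditions was possible, and with 1 library on each side of the RNA input difference no p-value was computed for it. The common biological coefficient of variation (BCV) was estimated with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with TMM factors and an intercept-only design. For gene lists, log2((TPM + 1) in library 2 / (TPM + 1) in library 1) was centred on the median of detected protein-coding genes, and the median of the detected members was placed as a percentile among 10000 random lists of the same size matched on mean expression, each member being replaced by 1 of the 100 nearest protein-coding genes. For single genes over 2-fold apart, the log2 TPM ratio had no pseudocount, was centred on the median of detected genes and was taken at a mean expected count of 100 or more. List levels are medians, over all measured members, of the mean TPM of the 2 libraries, placed as percentiles among detected protein-coding genes. The SD beside a list level is that of the values of the 2 libraries taken alone. A list level can therefore lie outside those 2 values. Of 6 pairs of lists, the mean log2(TPM + 1) was compared by a two-sided permutation test with 100000 permutations of list membership and Benjamini-Hochberg adjustment over the 6 pairs. The retained-intron share of a gene is the percent of its TPM in transcripts annotated as retained introns, at 100 or more expected counts in both libraries. Nuclear RNA can hold incompletely spliced transcripts, and their reads can be assigned to these isoforms. The share therefore cannot tell a retained intron from one not yet spliced out.

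The 16 gene lists, 10 lists of markers of other cell types, the pairs and the rule for named genes were fixed before the data were examined. Names were taken from the 3 highest detected members and the lowest of each list, 21 genes of the macrophage response chosen in advance, the 10 protein-coding genes and the 5 other genes of at least 200 nt effective length with the highest TPM, the 8 genes highest and the 8 lowest in library 2 relative to library 1 among protein-coding and lincRNA genes at a mean count of 100 or more, the 5 response genes with the highest retained-intron share at 500 or more counts, and the highest marker of each other cell type. Of the written symbols, Irg1, Emr1, Snhg4, Norad, Hbb-b1 and Hbb-b2 were not symbols of the annotation. Alternatives covered count minimums of 5 and 50, a pseudocount of 0.1, FPKM, posterior mean TPM, kallisto values, RLE and TMM scaling, effective lengths of at least 200 nt and each library alone. GC content was that of each gene's most counted transcript and was known for 99.9% of detected protein-coding genes.

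The main steps across genes were tested on simulated data. For the BCV, single genes and list differences, counts were drawn gene by gene, independently, from the means and sizes of these libraries. The retained-intron step used uniform random shares and the permutation test normal values, so their rates need not hold for these data. Genes regulated together, the GC trend and kallisto values were not simulated. A simulated BCV of 0.2 was estimated as 0.197 over 14063 genes. Of 200 genes changed 4-fold among 8942, 99.5% were found over 2-fold apart in the right direction, as were 2.26% of 8742 unchanged genes in either direction. Of 1000 unchanged lists of 20 genes, 4.9% fell outside the central 95% of random lists, and 72.7% did after a shift of 0.3 on the log2 scale. The number of lists was raised from 200 after that smaller run had given a higher share, and that run was not kept. The rule that an alternative changes a list difference when it crosses the central 95% was set after the values were seen. For the retained-intron percentiles, 6.9% of unchanged lists fell outside. The permutation test gave a p below 0.05 in 4.8% of null pairs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.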

Results

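RNA of the nucleoplasm, a fraction of the nucleus, was profiled in macrophages that had been exposed to Lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4, then rested, then exposed again for 40 min. The design held 1 group of 2 libraries and no unexposed or singly exposed cells, so the values describe that fraction in restimulated cells and not a change. The fraction also held mitochondrial mRNAs at a high level, given below, so its values need not be those of nuclear RNA alone. Library 1 held 19797829 expected counts and library 2 held 17213606. At 10 or more counts in both libraries 13757 genes were detected, of which 10979 were protein-coding and 1220 long non-coding. Across these genes, which are not independent replicates, log2(TPM + 1) had a Pearson r of 0.972 and a Spearman rho of 0.968 between the libraries, and the edgeR common BCV was 0.219.

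Primary cytokine and chemokine genes were among the most abundant protein-coding transcripts of this fraction. Tnf, the gene of tumour necrosis factor (chromosome 17, 35199381 to 35202007, mm10), stood at 1023 ± 3.97 TPM (SD, n = 2), and the neutrophil chemokine gene Cxcl2 at 530 ± 46.7 TPM. Ccl4 stood at 378 ± 137 TPM, Il1b at 237 ± 27.3 TPM and the anti-inflammatory cytokine gene Il10 at 36.3 ± 1.02 TPM. These SDs include the shift of the TPM scale between the libraries, so a small SD need not mean close values after centring. Centred on the median of detected genes, Tnf was 1.29-fold and Il1b 1.10-fold higher in library 2, although Tnf had the smaller SD. Of the 20 measured genes of this list 18 were detected, and 14 lay in the top 10% of detected protein-coding genes. The list median was 104 ± 9.28 TPM (SD, n = 2), at percentile 96.3 ± 0.483. The lowest detected member was Osm at 6.91 ± 1.09 TPM.

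Immediate-early genes, whose transcription needs no new protein, had a median at percentile 93.8 ± 0.650 (SD, n = 2), with 24 of 25 detected. Zfp36, whose product promotes decay of cytokine mRNAs, stood at 412 ± 4.95 TPM, Klf6 at 276 ± 18.4 TPM and Gadd45b at 233 ± 91.4 TPM. Egr1 was at 182 ± 11.3 TPM and Fos at 46.8 ± 7.44 TPM, while Fosb was the lowest detected at 0.705 ± 0.0636 TPM. All 23 genes of NF-κB and its negative feedback were detected, at percentile 93.4 ± 0.979. Among them Sqstm1 stood at 496 ± 26.9 TPM, the ubiquitin-editing enzyme gene Tnfaip3 at 457 ± 24.7 TPM, Tnfaip2 at 445 ± 127 TPM and Nfkbia, the gene of the inhibitor IκBα, at 384 ± 151 TPM. Socs3 was at 143 ± 31.3 TPM, Irak3, which encodes an inhibitor of TLR signalling, at 22.2 ± 10.6 TPM, and Socs1 was the lowest at 3.11 ± 1.91 TPM.

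Secondary inflammatory genes spread over a wide range. Saa3 stood at 1393 ± 853 TPM (SD, n = 2), Acod1, whose enzyme makes itaconate, at 1004 ± 177 TPM and Ccl5 at 924 ± 136 TPM. In contrast Il6 was at 6.52 ± 0.00707 TPM, Il12b at 2.16 ± 0.580 TPM, Il23a at 0.620 ± 0.0283 TPM and Nos2 at 13.1 ± 9.91 TPM. The list median was at percentile 62.4 ± 2.23, with 24 of 29 measured members detected and 8 in the top 10%. Library 1 alone gave percentile 60.6 and library 2 alone 57.5, both below the 62.4 from mean TPM. Interferon-stimulated genes were higher as a list, at percentile 98.0 ± 0.502, with 35 of 35 detected and 31 in the top 10%. The antiviral genes Rsad2, Ifit2 and Mx1 led it at 1109 ± 296, 793 ± 17.3 and 747 ± 500 TPM, and Cxcl10 was at 501 ± 129 TPM. The interferon-β gene itself, Ifnb1, was at 8.32 ± 3.84 TPM, and Cxcl9 was the lowest detected at 1.96 ± 2.23 TPM.

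The differences between fixed pairs of lists were tested within these libraries by permuting list membership across genes, which are not independent replicates. The test compares list means, while the differences that follow are of medians. Against secondary inflammatory genes the difference of means was 2.52 for primary cytokine and 1.59 for immediate-early genes. Against TLR4 pathway genes it was 2.95 for interferon-stimulated and 1.91 for feedback genes. The median log2(TPM + 1) of the primary cytokine and chemokine list lay 3.23 above that of the secondary inflammatory list (two-sided permutation test on list means, adjusted p = 0.00673, higher in 2 of 2 libraries). The interferon-stimulated list lay 3.06 above the genes of the TLR4 pathway, and the permutation test gave an adjusted p of 6e-05, from the smallest p that 100000 permutations can give. The NF-κB feedback list lay 1.52 above the TLR4 pathway list (permutation test, adjusted p = 0.00038), with 1.55 ± 0.311 over the libraries (SD, n = 2). The immediate-early list lay 2.52 above the secondary inflammatory list (permutation test, adjusted p = 0.0464). That last call was not kept with kallisto TPM (permutation test, adjusted p = 0.116), with detected members only (0.171) or in library 1 alone (0.0556). The TLR4 pathway list itself had its median at percentile 77.8 ± 1.204, with the co-receptor gene Cd14 at 200 ± 43.6 TPM, Irak2 at 88.2 ± 39.3 TPM, Tbk1 at 83.4 ± 26.8 TPM, Tlr4 at 17.1 ± 2.29 TPM and Lbp at 0.755 ± 0.134 TPM.

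**Figure D1:**
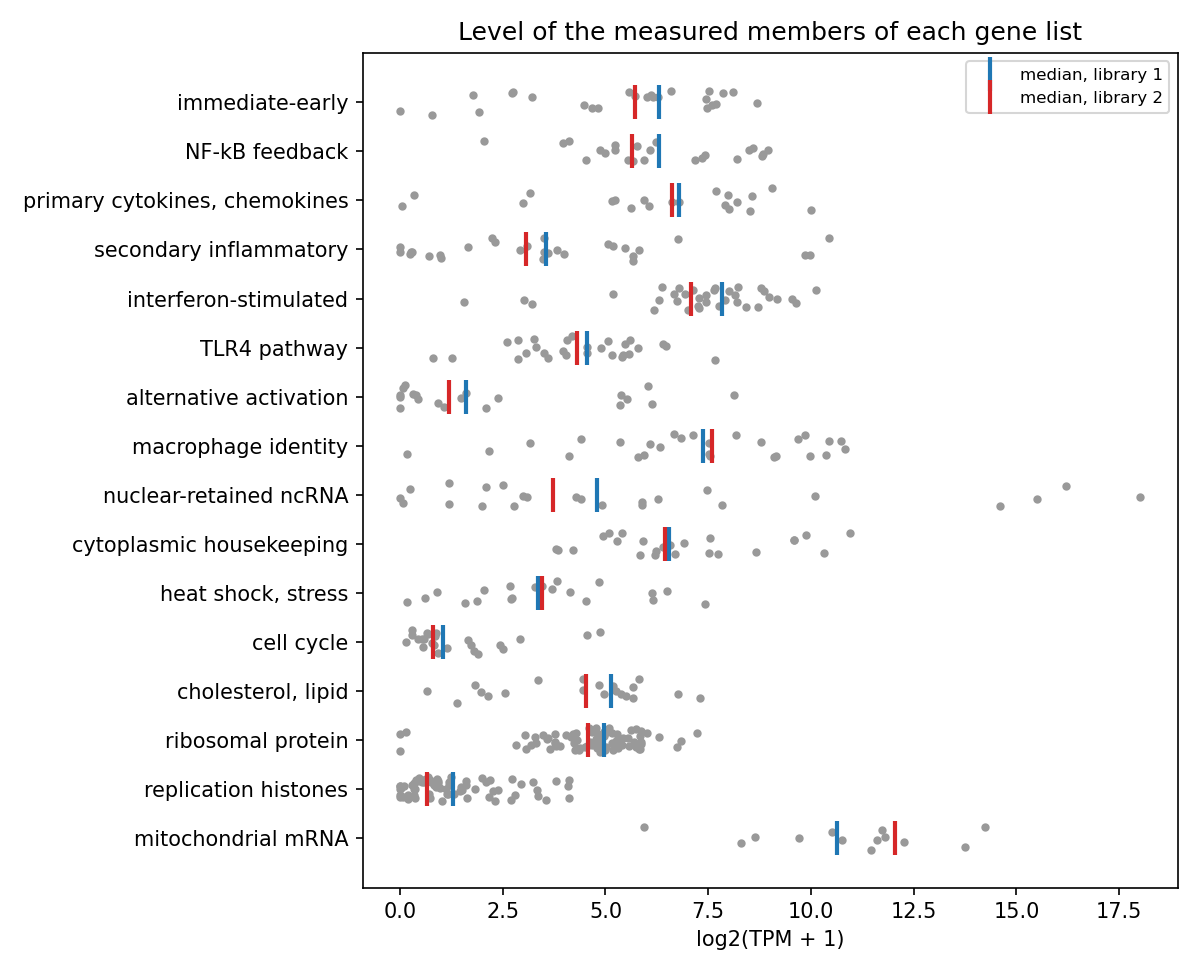
Level of each measured member (grey points, mean of the 2 libraries) of the 16 gene lists as log2(TPM + 1), with the list median in library 1 (blue bar) and library 2 (red bar). Taken over mean TPM, the medians of the interferon-stimulated and macrophage identity lists lie at percentiles 98.0 and 98.1 of detected protein-coding genes. That of the alternative activation list lies at 17.6.

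Genes of macrophage identity had a median at percentile 98.1 ± 0.773 (SD, n = 2), with 26 of 27 measured members detected. Gpnmb stood at 1813 ± 177 TPM, the lysosomal protease genes Ctsb and Ctsd at 1695 ± 108 and 1379 ± 0.509 TPM, Lyz2 at 1311 ± 155 TPM, Adgre1, which encodes F4/80, at 565 ± 172 TPM and the receptor gene Csf1r at 288 ± 42.3 TPM. Ccr2 was the lowest detected member at 3.52 ± 1.55 TPM. Genes of alternative activation were far lower, with a median at percentile 17.6 ± 2.82 and 13 of 20 detected, or at 4.77 with 8 detected at a minimum of 50. Library 1 alone gave percentile 22.1 and library 2 alone 18.1, both above the 17.6 from mean TPM. Stab1 at 277 ± 169 TPM, Trem2 at 69.3 ± 13.2 TPM and Tgfb1 at 65.0 ± 5.04 TPM led that list, and Irf4 was its lowest detected member at 0.345 ± 0.0636 TPM. The difference of the medians was -6.31 on the log2 scale and that of the means -4.81 (permutation test on means, adjusted p = 6e-05, lower in 2 of 2 libraries).

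Markers of other cell types were low. The median member stood at 0.045 TPM for T cell markers, 0.0575 for B cell, 0 for natural killer cell, 0.07 for neutrophil, 0 for mast cell or basophil, 0.305 for dendritic cell, 0.07 for erythroid, 0.495 for megakaryocyte, 0.05 for fibroblast and 0.113 for endothelial cell markers. Single members stood above their lists. The highest were Bst2, an interferon-induced gene, at 176 ± 108 TPM (SD, n = 2), Csf3r at 91.1 ± 17.8 TPM, Cd28 at 32.0 ± 11.1 TPM, Vwf at 20.8 ± 0.799 TPM and Kdr at 11.2 ± 2.28 TPM. The highest of the remaining lists were Alas2 at 2.26 ± 0.693, Klrk1 at 1.25 ± 0.0283, Kit at 0.840 ± 0.467, Cd79b at 0.560 ± 0.212 and Fn1 at 0.410 ± 0.396 TPM.

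Protein-coding genes took 71.6% ± 1.87 of the expected counts (SD, n = 2) and long non-coding genes 14.4% ± 2.74. The nuclear RNA Malat1 alone took 12.3% of the counts of library 1 and 9.64% of those of library 2. Small non-coding genes took 6.40% ± 1.36 of counts but 58.8% and 62.5% of TPM, since TPM divides by their short lengths. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, reached 265379 ± 65271 TPM, Rpph1 75031 ± 36110 TPM and Rmrp 46723 ± 8493 TPM. Rmrp overlaps a second gene of the same symbol and its reads cannot be divided with certainty. Neat1 was at 1096 ± 736 TPM and Malat1 at 24728 ± 2528 TPM. Gm37376 had 5528 TPM in library 1 and 825 TPM in library 2, or 2642 and 2146 TPM with kallisto. These TPM are not centred, and the kallisto scale shifts between the libraries. The centred log2 ratio of Gm37376 in library 2 over library 1 was -2.37 with RSEM and -1.16 with kallisto. Gm37376 lies within Malat1 on the other strand, so their reads may not be divided with certainty. The list of non-coding RNAs named nuclear-retained was set in advance, and whether its members stay in the nucleus was not checked. It also holds Gas5 and several Snhg transcripts, so its median need not describe retained RNA alone. The median of this list lay 2.27 below that of cytoplasmic housekeeping genes on the log2 scale. The difference of means was -1.11 and did not pass (permutation test on means, adjusted p = 0.351). With TPM rescaled over genes of at least 200 nt outside the mitochondrial genome, chosen after seeing the data, the permutation test gave an adjusted p of 0.00408, but that cut takes Rn7sk, Rpph1 and Rmrp out of the list. The same rescaling with these members kept, also chosen after seeing the data, gave 0.268 by the permutation test. Housekeeping genes were at percentile 95.7 ± 0.792, led by Fth1, Actb and Ftl1 at 1963 ± 337, 1270 ± 90.7 and 941 ± 121 TPM.

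Among the remaining lists, heat shock and stress genes had a median at percentile 59.9 ± 5.95 (SD, n = 2), led by the chaperone gene Hspa5 at 172 ± 71.8 TPM. Cholesterol and lipid genes were at percentile 84.6 ± 1.82, led by Pltp at 156 ± 23.4 TPM and the cholesterol exporter gene Abca1 at 108 ± 5.79 TPM. Ribosomal protein genes were at percentile 83.7 ± 0.245, with 77 of 80 detected, but at 50.1 by expected counts, which are not scaled by length. Cell cycle genes were at percentile 10.4 ± 0.979, with Mki67 at 28.1 ± 4.55 TPM as the highest, and at 17.2 with kallisto and 1.11 at a minimum of 50. For this list library 1 alone gave percentile 12.4 and library 2 alone 11.1. Replication-dependent histone genes were at percentile 11.8 ± 5.72, with 25 of 70 detected, 39 in library 1 alone and 8 at a minimum of 50. The percentile was 0 by expected counts, 7.61 with kallisto and 1.51 at a minimum of 50. Their near-identical copies share reads.

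Among the gene lists, the libraries differed most in mitochondrial mRNAs. The median of that list was 1596 TPM in library 1 and 4217 TPM in library 2, at percentile 99.98 by mean TPM. Both libraries thus held RNA from outside the nucleus, and how much it adds to other levels was not measured. Mitochondrial genes took 2.63% of the counts of library 1 (Wilson 95% interval 2.62% to 2.63%) and 6.60% of those of library 2 (6.59% to 6.61%). The 12 detected mitochondrial mRNAs had a median centred log2 ratio of 1.53 in library 2 relative to library 1, and 10 of the 12 were higher. The median lay above all 10000 random lists, which could not be fully matched on expression. Mean TPM was 19145 for mt-Atp8 and 13659 for mt-Co1. For Psap, the highest protein-coding gene outside the mitochondrial genome, it was 3668. Examples of the 12 were mt-Co1 at 8493 TPM in library 1 and 18824 TPM in library 2, and mt-Nd1 at 1698 and 5057 TPM. In contrast mt-Co3 was at 406 and 218 TPM, but higher in library 2 with kallisto, at 460 and 1529 TPM before centring. Its centred log2 ratio was -0.52 with RSEM and 0.87 with kallisto. Pseudogenes took 1.23% of counts (1.23% to 1.24%) and 2.28% (2.27% to 2.29%), a difference that turned with kallisto, at 7.68% and 5.68%. Most of that kallisto share was in Gm12895 and Gm12896, which had no RSEM count. Each took 868618 kallisto counts in library 1 and 494968 in library 2. Pseudogenes that share sequence with mitochondrial genes were higher in library 2 with both programs, at 0.623% and 1.72% with RSEM and 0.257% and 0.806% with kallisto. The pseudogenes Gm28661, Gm10925 and Gm28437, side by side on chromosome 1 from 24613189 to 24615565, had 4335, 2897 and 1882 TPM in library 1 and 9103, 7926 and 5462 TPM in library 2. With kallisto Gm10925 went the other way, at 32.4 and 0.481 TPM, and Gm28437 was at 58.3 and 1375 TPM, all before centring. Ribosomal RNA genes took 0.0608% and 0.00383% of counts, or 0.196% and 0.0842% with kallisto. Long non-coding genes took 16.3% (16.3% to 16.3%) in library 1 and 12.4% (12.4% to 12.4%) in library 2. These differences follow the replicate number and the labelled RNA input alike and have no replicate check.

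Response lists also differed between the libraries, after a median shift of -0.27 on the log2 scale of all detected protein-coding genes was removed. The primary cytokine and chemokine list had a median of 0.30 higher in library 2, at percentile 99.99 of matched random lists, with 14 of 18 detected members higher, and of 0.64 with kallisto TPM. Ccl3, at 314 and 422 TPM, was chosen after its values were seen. The NF-κB feedback list had a median of -0.33, at percentile 0.93, with 19 of 23 members lower. Kallisto TPM gave 0.064 at percentile 4.30, inside the central 95% but still below most matched lists, so its sign shows no reversal. Since most lists matched to the feedback list lay above 0 with kallisto, medians from that program are to be read by percentile, not by sign or size. With a trend on GC content removed, chosen after seeing the data, the feedback median was -0.27 at percentile 3.12, inside the central 95%. Nfkbia was at 491 TPM in library 1 and 277 TPM in library 2. Macrophage identity genes had a median of 0.21 (percentile 99.98) and cytoplasmic housekeeping genes 0.17 (percentile 99.92), or 0.56 and 0.45 with kallisto TPM. Replication histone genes had a median of -0.44, below all 10000 random lists, and of -0.22 at percentile 9.98 with a count minimum of 50. The interferon-stimulated list at -0.24 (percentile 4.48) and the immediate-early list at -0.22 (percentile 5.14) lay inside the central 95% of random lists, though the former was at -0.29 and percentile 0.63 with the GC trend removed, and with kallisto TPM both medians were above 0, at 0.11 and 0.076, yet still at percentiles 6.67 and 20.54 of matched lists. The medians of the others lay inside that range: secondary inflammatory at -0.09, TLR4 pathway at -0.15, alternative activation at 0.12, nuclear-retained RNA at -0.02, heat shock at 0.16, cell cycle at 0.21, cholesterol at 0.00 and ribosomal protein at -0.01. Some of these left that range under an alternative: secondary inflammatory at percentile 1.00 with kallisto TPM, alternative activation at 99.36, heat shock at 99.85 and ribosomal protein at 99.08 with the GC trend removed, and cell cycle at 99.31 and heat shock at 97.83 with a count minimum of 50. With kallisto TPM the TLR4 pathway median was 0.17 (percentile 75.84), cell cycle -0.22 (44), ribosomal protein 0.20 (74.29) and cholesterol 0.20 (89.59), all still inside that range. The nuclear-retained median was 0.037 with a count minimum of 50 and 0.045 with a pseudocount of 0.1.

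**Figure D2:**
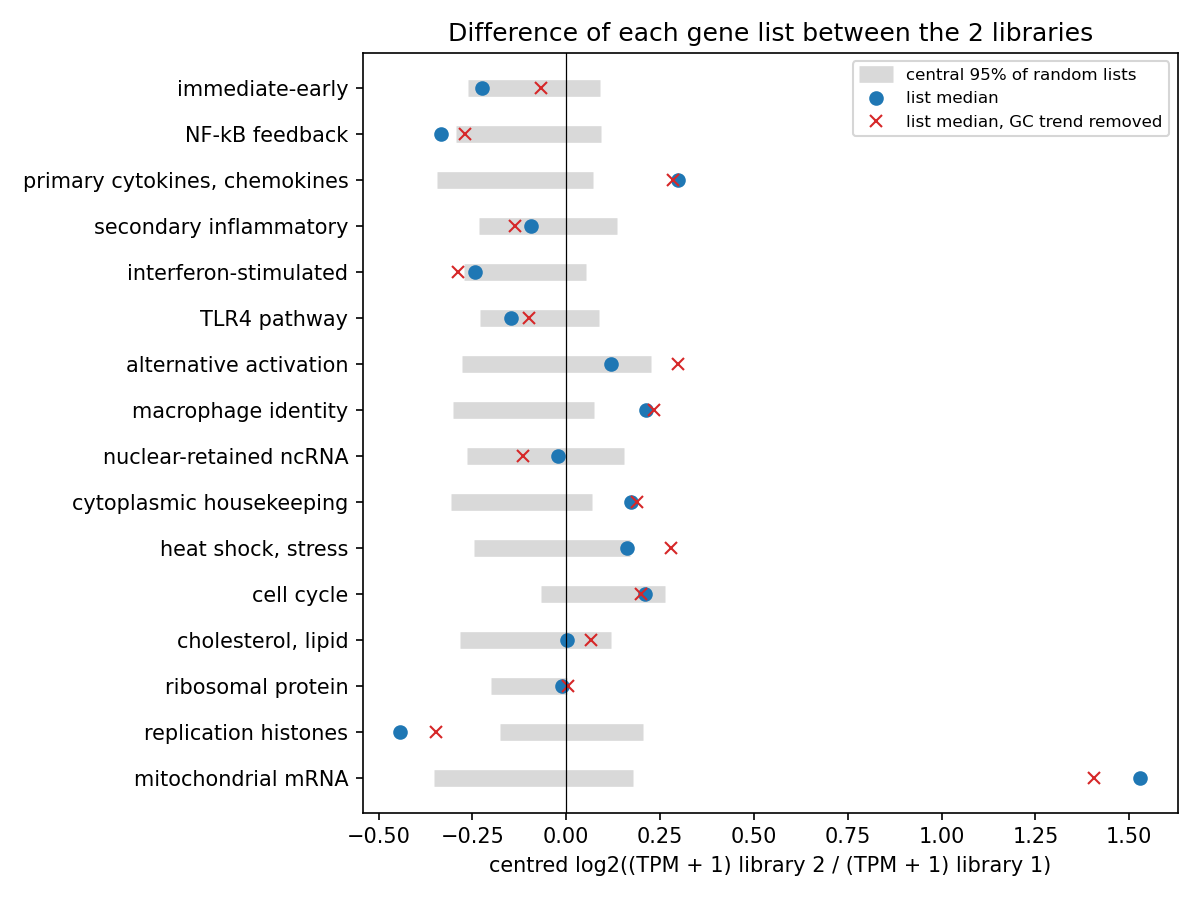
Median centred log2 ratio of TPM + 1 in library 2 over library 1 for the detected members of each list (blue points), the same after a trend on GC content was removed (red crosses), and the central 95% of 10000 matched random lists (grey bars). The mitochondrial mRNAs lie at 1.53, far to the right of their random lists.

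Of 8935 genes with a mean count of 100 or more, 338 (3.78%) were over 2-fold apart, 157 higher and 181 lower in library 2. Without centring the split was 53 higher and 756 lower. At a simulated BCV of 0.2, 2.26% of unchanged genes were over 2-fold apart. That BCV is close to the 0.219 estimated from these same libraries, whose spread includes the gaps of the 338 genes. The simulation also used counts without length estimates. It therefore cannot show how many of the 338 differ by more than the spread between libraries. A further 7 genes at that depth were listed at 0 in library 2 and were left out. Of the 338 genes, 94 were as far higher and 125 as far lower by TMM-scaled counts, and 73 and 91 by kallisto TPM, so single folds depend on the estimate. Among protein-coding and lincRNA genes at that depth, the highest in library 2 included Gbp10, at 3.02 and 20.4 TPM, and the overlapping Gm43302, at 0.53 and 7.97 TPM, which share reads, then Cox20 at 5.94 and 21.3 TPM and Zfp993 at 17.1 and 60.0 TPM, besides mt-Atp8, mt-Atp6, mt-Nd1 and mt-Nd4. The lowest of these classes were Zbed6 at 3.08 and 0.18 TPM, the second Rmrp gene, Inpp4b at 5.99 and 0.68 TPM, Gm10382, Gm26669, Bmp1 at 3.16 and 0.58 TPM, Slc13a3 at 39.8 and 7.44 TPM and Adamtsl4 at 33.5 and 6.77 TPM. Part of some gaps lies in the estimated effective length: Gbp10 had 215 and 368 counts at 3324 and 799 nt, Zfp993 281 and 449 at 767 and 331 nt, Inpp4b 155 and 88 at 1208 and 5686 nt and Adamtsl4 1150 and 558 at 1600 and 3643 nt. With kallisto, Adamtsl4 at 31.4 and 30.5 TPM and Gm26669 at 5.46 and 5.47 TPM were under 2-fold apart after centring, and Zbed6 was at 0.0264 and 0 TPM. Long non-coding genes had 35 lower and 5 higher among 384.

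Isoforms annotated as retaining an intron made up a median of 23.6% ± 2.04 of gene TPM (SD, n = 2) over 5058 protein-coding genes that have such an isoform, or 12.8% by expected counts and 29.9% with kallisto TPM. Across these genes the shares had a Spearman rho of 0.854 between the libraries. These shares may include transcripts still being spliced, so a high share need not mean a lasting intron-retaining isoform. Among response genes with 500 or more counts in both libraries the highest shares were in Tnip3 at 78.3% ± 1.36, Nfkb1 at 72.6% ± 8.05, Irf7 at 61.8% ± 4.31, Oasl2 at 60.6% ± 1.54 and Ifih1 at 60.1% ± 4.23. For Ifih1 kallisto gave 30.98% and 36.1%. List medians were 32.9% ± 2.65 for interferon-stimulated, 29.7% ± 7.497 for NF-κB feedback, 28.9% ± 0.928 for primary cytokine, 25.6% ± 7.12 for secondary inflammatory and 19.4% ± 0.379 for immediate-early genes, all inside the central 95% of expression-matched lists in both libraries. In contrast, 10 macrophage identity genes had a median of 2.94% ± 2.09, at percentile 0 of matched lists in both libraries, and 20 housekeeping genes had 10.7% ± 2.63, at percentiles 0.06 and 0. With kallisto TPM these percentiles were 0.06 and 0 for the former and 0.02 and 0 for the latter. The 56 ribosomal protein genes had 18.9% ± 3.11, at percentiles 1.12 and 0.33, but at 29.3 and 1.99 with kallisto TPM, and at 4.74 and 6.28, inside the central 95%, with gene span matched as well.

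**Figure D3:**
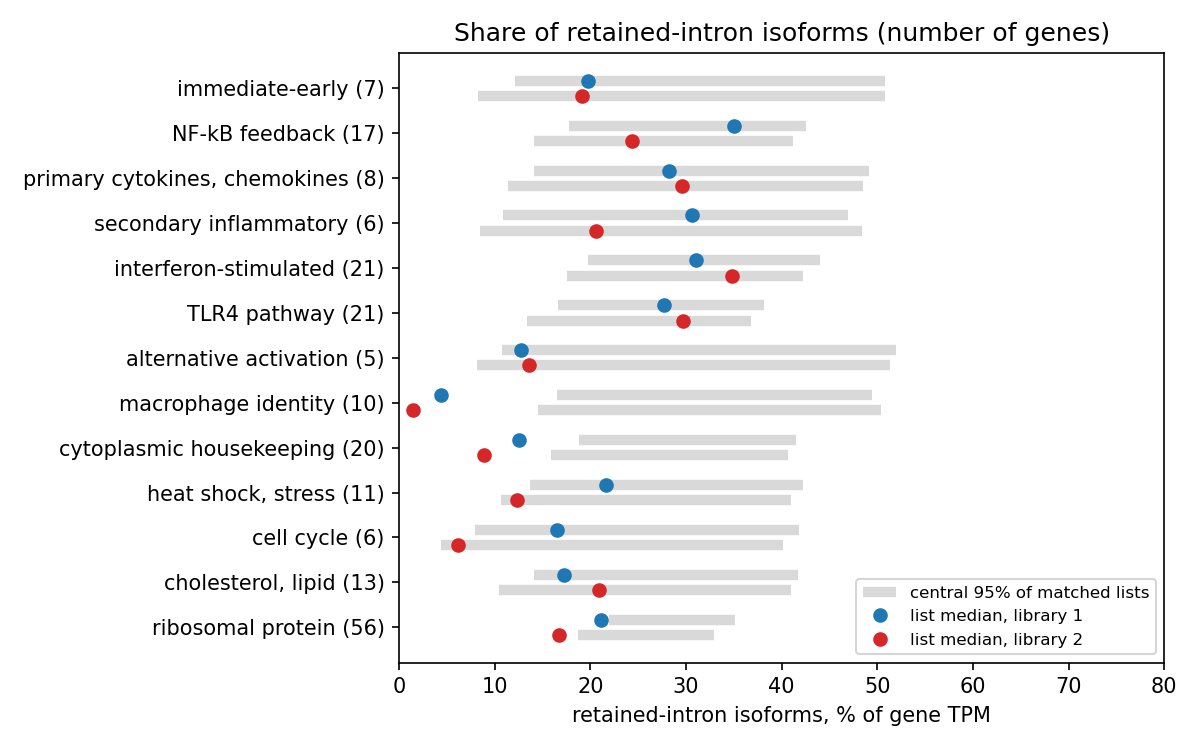
Median percent of gene TPM in retained-intron isoforms per gene list in library 1 (blue) and library 2 (red), with the central 95% of 10000 expression-matched lists (grey bars) and the number of genes in parentheses. The macrophage identity, housekeeping and ribosomal protein medians lie to the left of their bars in both libraries.

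RSEM and kallisto gene values had a Spearman rho of 0.934 in library 1 and 0.928 in library 2 over 13748 detected genes, and of 0.958 and 0.956 over 10971 protein-coding genes. These correlations are across genes, which are not independent replicates.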

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

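The tests of cytosol carry-over and of nuclear copies for the mitochondrial pattern, of a weaker restimulation, and of GC content for the immediate-early list alone and the feedback list alone were chosen after the results were seen. Apart from a weaker restimulation, no biological explanation was tested, since the design has 1 group.

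Sequences outside the gene comparisons drew reads above the 3 counts that a count of 0 allows. PhiX, a sequencing control, took 130047 expected counts in library 1 and 38206 in library 2. The ERCC spike-in sequences took 4 and 21 estimated counts in the kallisto tables, where the RSEM tables give 0. The 5 genes with the most kallisto counts among those with no RSEM count in either library, Gm12895 and Gm12896 on chromosome 4, annotated as processed pseudogenes, and Gm23935, Gm24245 and Gm24270, annotated as miRNA genes, took 2569562 kallisto counts in library 1 and 1189280 in library 2. They hold 74.7% and 46.9% of the kallisto TPM.

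Mitochondrial mRNAs were higher in library 2, with a median centred log2 ratio of 1.53. After the trend on GC content was removed the median was 1.41, which argues against that trend, as fitted, as the whole cause. The fit rests on other genes, whose lowest GC decile ended at 41.2% GC and had a median ratio of 0.145. The mitochondrial list had a median GC of 36.5%, so a steeper GC effect at that low end stays open. Carry-over of cytosol would raise cytoplasmic mRNAs too, by less where a transcript is already abundant in the fraction. The ribosomal protein median was -0.010 with RSEM (percentile 95.39 of matched random lists) and 0.20 with kallisto (74.29). Housekeeping genes were higher by 0.17 and 0.45 (99.92 and 99.89), and macrophage identity genes by 0.21 and 0.56 (99.98 and 100). The ribosomal protein median rose with kallisto while its percentile fell, so the kallisto medians cannot be read as larger rises. Carry-over of cytosol stays open. Reads moved between mitochondrial genes and their nuclear copies would leave the sum unchanged, and the summed share of mitochondrial genes and the 21 pseudogenes that share a 31-base stretch with them differed 2.56-fold with RSEM and 2.63-fold with kallisto. Summed with all pseudogenes the share differed 2.30-fold with RSEM but 1.17-fold with kallisto, where pseudogenes without such a stretch hold most of the pseudogene counts. Mitochondria carried along with the fraction, the labelled RNA input and a difference between the cultures stay open and were not tested.

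The NF-κB feedback list was lower in library 2, and the immediate-early and interferon lists leaned the same way inside the range of random lists. With the GC trend removed the largest of the 3 absolute medians was 0.29, that of the interferon list, which argues against GC content as the whole cause for that list. The feedback median was -0.27, now inside its random range at percentile 3.12, so GC content stays open for it. It came inside because its median moved from -0.33, while the lower end of its range moved from -0.294 to -0.281. The immediate-early median went from -0.22 to -0.067, so that GC content may account for that list. A weaker restimulation predicts lower primary cytokine transcripts, and that list had a median of 0.30. This does not settle it, because carry-over of cytosol could raise the same list.

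The primary cytokine list was higher in library 2. GC content is argued against as the whole cause by a median of 0.28 after its trend was removed. Carry-over of cytosol may contribute: genes in the quintile with the lowest retained-intron share had a median ratio 0.13 above those in the highest quintile, between the bounds of 0.05 and 0.2 set before that test, so it stays open.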

How the results depend on the processing

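Alternatives that removed the GC trend, rescaled TPM or took the correlation between libraries over protein-coding genes alone were chosen after seeing the data. No paired analysis was possible because the design has 1 group. Of 48 alternatives to the differences between fixed list pairs, 44 kept direction and side of the threshold and none reversed. Immediate-early against secondary genes was 1.91 with kallisto TPM, 2.43 with detected members only and 2.66 to 2.75 with single libraries, past the threshold in library 2 alone and not in library 1 alone. The nuclear RNA against housekeeping difference was -3.63 with TPM rescaled without short genes, which leaves 21 of 24 nuclear members, and -2.32 with all members kept, so the cut and not the scaling moved it. Depth limits what a count of 0 shows, to 0.152 CPM in library 1 and 0.174 CPM in library 2. Genes over 2-fold apart numbered 1480 of 14481 at a mean count of 10 or more, and 809 of 8935 at 100 or more without centring. The BCV was 0.252 without a filter, 0.199 at a minimum of 50 and 0.212 at 200 nt or more. The correlation was 0.971 at a minimum of 50, 0.975 with kallisto, 0.977 for protein-coding genes and 0.968 with a pseudocount of 0.1. RSEM against kallisto was 0.766 without a filter and 0.957 for protein-coding genes. The retained-intron share was 12.8% by expected counts and 29.9% with kallisto. By TPM the class shares were 24.9% protein-coding, 5.22% long non-coding, 60.7% small non-coding and 2.84% pseudogene; by kallisto counts they were 66.3% protein-coding and 6.68% pseudogene.

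Percentiles against a background at a minimum of 50 were 92.3 for immediate-early, 91.8 for feedback, 95.4 for primary cytokine, 53.7 for secondary, 72.7 for TLR4 pathway, 94.7 for housekeeping and 4.77 for alternative activation genes, of which 8 passed that minimum. By expected counts they were 91.0 for immediate-early, 93.6 for primary cytokine, 54.7 for secondary, 14.1 for alternative activation, 96.2 for macrophage identity, 62.9 for nuclear RNA and 91.6 for housekeeping genes. With kallisto they were 90.6 for immediate-early, 97.3 for primary cytokine and 67.6 for nuclear RNA. Single libraries gave 18.1 to 22.1 for alternative activation, 57.5 to 60.6 for secondary and 77.7 to 79.5 for TLR4 pathway genes.

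With kallisto TPM most random lists matched to the feedback, immediate-early and interferon lists lay above 0. The sign of a median alone therefore shows no direction there. The differences between libraries were 0.064 for feedback (percentile 4.30, now inside), 0.076 for immediate-early (20.54), 0.11 for interferon (6.67), 0.17 for TLR4 pathway (75.84), 0.20 for cholesterol (89.59), 0.20 for ribosomal protein (74.29), 0.45 for housekeeping, 0.56 for macrophage identity, 0.64 for primary cytokine, 1.96 for mitochondrial, -0.22 for cell cycle (44) and -0.11 for secondary inflammatory genes (percentile 1.00, now outside). With TMM-scaled counts they were -0.13 for interferon, -0.060 for TLR4 pathway, 0.34 for macrophage identity and 0.017 for cell cycle genes. With the GC trend removed they were -0.067 for immediate-early, -0.27 for feedback (percentile 3.12, now inside the central 95% of random lists), 0.30 for alternative activation (percentile 99.36), 0.28 for heat shock (99.85), -0.29 for interferon (0.63) and 0.0034 for ribosomal protein genes (99.08), the last 4 now outside it. A minimum of 50 gave -0.22 for histone genes (percentile 9.98, now inside), and 0.36 for cell cycle (99.31) and 0.19 for heat shock genes (97.83), both now outside, and a pseudocount of 0.1 gave -0.61 for histone and 0.054 for ribosomal protein genes. The cause was not tested for these.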

Other observations

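Transcripts of genes beyond the response stood high in this fraction. The lysosomal gene Psap was at 3668 ± 346 TPM (SD, n = 2) and H2-K1, which presents antigen, at 3157 ± 18.2 TPM. Mir155hg, the host transcript of a microRNA of the inflammatory response, was chosen after its values were seen and had 240 and 211 TPM in libraries 1 and 2. Xist had 190 and 161 TPM, while 4 Y-linked genes, Ddx3y, Kdm5d, Eif2s3y and Uty, had 0 expected counts in both libraries, although kallisto gave them TPM of 0.106 to 2.61. These Y-linked genes and their values were added after seeing the data.

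It was hypothesised that response genes hold more retained-intron isoforms than other genes of the same expression. The 59 response genes with such an isoform had a median of 28.2% in library 1 and 25.5% in library 2, against medians of 32.1% and 29.1% in matched lists. They lay at percentiles 18.4 and 17.98, so the hypothesis was not borne out. With gene span matched as well the percentiles were 29.89 and 33.3.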
